A study of Arabidopsis thaliana with 6 samples.

How the data were processed

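RNA from leaves of 3 Col-0 and 3 rlt1-1 rlt2-1 samples was profiled on Affymetrix arrays with 22810 probe sets. Per the labels' protocols, total RNA was purified with a Qiagen RNeasy kit, copied into cDNA from a T7 oligo(dT) primer and amplified by in vitro transcription into biotin-labelled RNA, so transcripts with a poly(A) tail were favoured. The values are log2 signals, 1 per probe set and array, deposited by the authors as a table of the whole series. RMA and Partek are named in the submitters' processing notes, with no version or order given. The log2 scale was taken from the range of the values, between 2.94 and 14.34, and from these notes. RMA combines the probes of a probe set after a normalization between arrays, so the total signal is made alike on every array and a change shared by most transcripts would not be seen. The array medians before any further step were 5.79, 5.83 and 5.86 in Col-0 and 5.80, 5.79 and 5.80 in the mutant. The number of arrays limits the precision.

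The 64 array control probe sets were left out of the tests of genes, which left 22746. Gene names came from a table that pairs the array's probe sets with genes, updated through the Entrez gene number with NCBI's gene table of assembly TAIR10.1. Of the tested probe sets, 13513 had 1 gene in that table, 503 had several and were left unnamed, and 8730 had no entry and are unnamed here. Through the Entrez number 13436 matched a gene of the reference table. Those with no match kept the name in the first table. The 13513 probe sets with 1 gene make 13355 genes, of which 1557 carry a symbol beyond the locus code. Where 2 or more probe sets named a gene, the one with the highest mean over all arrays was used. Gene spans and the order of genes along chromosomes came from the table of assembly TAIR10.1. Names of probe sets that end in _s_at or _x_at mark possible sharing between genes.

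Groups and replicate numbers came from the sample titles. The mutant was compared with Col-0 by limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) over all 6 arrays with no covariate, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. A second count required a change of at least 2-fold. Errors of single groups are SDs over 3 arrays, and errors of log2 fold changes are limma's moderated standard errors. The procedure was tested on simulated arrays with the real means and spreads for this comparison, in which 200 of 22746 probe sets were changed. Of 50 probe sets changed by 0.25 log2 units 6% were found, of 50 changed by 0.5 50% were found, of 50 changed by 1 94% were found, and of 50 changed by 2 100% were found, while 4 unchanged probe sets were called. A simulation with no change gave 0 calls. With so few changed probe sets the adjustment is stricter than in the real data, where 9265 were called. The shares found at 0.25 and 0.5 log2 units therefore do not apply to the real comparison. Errors were drawn separately for each probe set, so the false calls leave out array effects shared by many genes.

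Before the data were examined, 24 gene lists with 352 members were fixed. Members were matched by locus, and 8 were left out because the reference did not pair the locus with the name given. Lists were tested with limma's camera (preset correlation 0.01, 1 probe set per gene, against all other named genes) with adjustment over the lists tested, and again with an estimated correlation and with fry. The genes named in the text followed a rule fixed at the same time. It took RLT1, RLT2, CHR11, CHR17, FLC, FT, SOC1 and SEP3 always. It took the 12 largest rises and the 12 largest falls among probe sets with 1 gene, an adjusted p under 0.05 and groups that do not overlap. It took up to 4 called members of each list, or up to 2 with the smallest p where none was called, given as values. Members beyond this rule are given as values to complete a list. RNA quality was read from the 3' and 5' probe sets of actin, GAPDH and ubiquitin controls.

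Alternatives fixed beforehand were the replicate number as a block, a further quantile normalization, centring on array medians, leaving out the dimmest 30% or 50% of probe sets, an intensity trend with a robust prior, array weights, an unmoderated equal-variance test, gene-specific probe sets alone, leaving out each array in turn, other thresholds and other set tests. Chosen after the data were seen were the centring on spike controls, lists of at least 3 measured genes alone, groups of at least 6 genes that share a symbol stem, plastid-encoded genes as a group, the relation with gene length, the removal of its trend and the tests of neighbouring genes.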

Results

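Gene expression was measured on 6 Affymetrix arrays hybridised with labelled RNA from Arabidopsis thaliana leaves. Of these, 3 arrays came from the wild-type accession Col-0 and 3 from the double mutant rlt1-1 rlt2-1. The plants were 15 days old, grew under 16 h of light and 8 h of darkness at 21 °C, and received no treatment. RLT1 and RLT2 (RINGLET1 and RINGLET2) encode DDT-domain proteins that bind the ISWI chromatin remodelers CHR11 and CHR17, and loss of both genes is known to alter leaf development and to advance flowering. The comparison between the 2 groups asks which transcripts depend on the RLT proteins in young leaves. The array medians lay between 5.79 and 5.86 on the log2 scale, over values from 2.94 to 14.34. Arrays of one group correlated at 0.997 to 0.999 (Pearson's r over 22746 probe sets), and arrays of different groups at 0.979 to 0.980. The first principal component, with 86.2% of the variance, separated the groups. Col-0 replicate 1 stood apart from the other Col-0 arrays on the second component, with 6.02% of the variance. The labels do not say whether the replicates came from separately grown plants, so the p-values measure only the spread between these samples, which may be technical.

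The transcriptome of rlt1-1 rlt2-1 leaves differed widely from that of Col-0 leaves. In limma's moderated test, 9265 of 22746 probe sets (40.7%) differed at an adjusted p under 0.05, with 4669 higher and 4596 lower in the mutant. Most changes were small, and the median change among these probe sets was 1.36-fold. A change of at least 2-fold was found for 1001 probe sets, of which 406 were higher and 595 lower. At 4-fold, 30 probe sets were higher and 87 lower. The values of the 2 groups did not overlap for 11566 probe sets (50.8%), where chance gives 10% for 3 arrays against 3. When each array was instead centred on the bacterial and phage spike controls, a scaling chosen after the data were seen, 5795 probe sets were higher and 3532 lower.

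RLT1 and RLT2, the mutated genes, were not analysed here, because the table of probe sets and genes used here paired no probe set with them, nor with CHR11, FLC, FT, SOC1 or SEP3. The group labels were therefore not checked against the mutated genes. The level of CHR17, one of the ISWI partners, was 7.27 ± 0.11 (SD, n = 3) in Col-0 and 7.23 ± 0.02 in the mutant on the log2 scale, with a log2 fold change of -0.04 ± 0.07 (SE) that did not pass the test (adjusted p = 0.710).

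Among probe sets with 1 named gene, the 12 largest decreases lay between 5.89-fold and 14.9-fold; probe sets with no named gene fell by up to 17.57-fold. AT4G21870, which encodes a small heat shock protein-like protein, fell from 11.35 ± 0.12 (SD, n = 3) in Col-0 to 7.45 ± 0.06 in the mutant, which is 14.9-fold lower (log2 fold change -3.90 ± 0.07 SE, adjusted p = 2.95e-08). The plant defensin gene PDF1.2, a marker of jasmonate and ethylene signalling, was 6.29-fold lower (log2 fold change -2.65 ± 0.20 SE, adjusted p = 1.34e-05). Its relative PDF1.2b was 7.90-fold lower, on a probe set that can be shared with other genes. Of the 7 genes with a PDF symbol, grouped by symbol alone, these 2 fell and 4 rose. GLR2.7, a glutamate receptor-like channel gene, fell 7.67-fold. The receptor-like kinase gene AT4G27300 fell 6.92-fold, AT1G57630, which encodes a TIR-domain protein, 6.84-fold, and AT2G43620, of the chitinase family, 6.04-fold. AT4G20860, of the berberine bridge enzyme-like oxidases, fell 6.61-fold, and AT3G23550, of the MATE efflux transporters, 8.17-fold. The other genes among these 12 decreases were AT1G76960, lower by 9.02-fold, AT5G41900, lower by 7.14-fold, and AT5G12420, lower by 5.89-fold. The mutant levels of GLR2.7 (4.15) and AT5G12420 (4.24) lay near the low end of the scale, where the lower quartiles of the arrays were 4.077 to 4.099, so their folds are approximate.

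Among probe sets with 1 named gene, the 12 largest increases lay between 4.34-fold and 7.29-fold; probe sets with no named gene rose by up to 9.54-fold. AT1G54050, which encodes a cytosolic small heat shock protein, rose from 5.15 ± 0.14 (SD, n = 3) in Col-0 to 8.02 ± 0.11 in the mutant, which is 7.29-fold higher (log2 fold change 2.87 ± 0.09 SE, adjusted p = 1.63e-07). AT5G45670, of the GDSL lipases, rose 6.94-fold, AT5G48490, of the lipid transfer proteins, 6.15-fold, and AT1G23205, of the invertase and pectin methylesterase inhibitors, 5.10-fold. GI (GIGANTEA), a clock gene that promotes flowering in long days, rose 5.03-fold, from 5.29 ± 0.19 (SD, n = 3) to 7.62 ± 0.04 (adjusted p = 6.10e-07). AT5G50915, which encodes a bHLH transcription factor, rose 4.94-fold, and the glutathione transferase gene GSTU26 4.68-fold from 4.41. The other increases were those of AT4G19430, which lay near the low end of the scale in Col-0 at 3.82, and of AT4G16880, AT2G39920, AT4G37290 and AT2G23910. Each gene named from these arrays was read by 1 named probe set. The groups did not overlap for any of these 24 genes, by the rule that chose them.

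**Figure D1:**
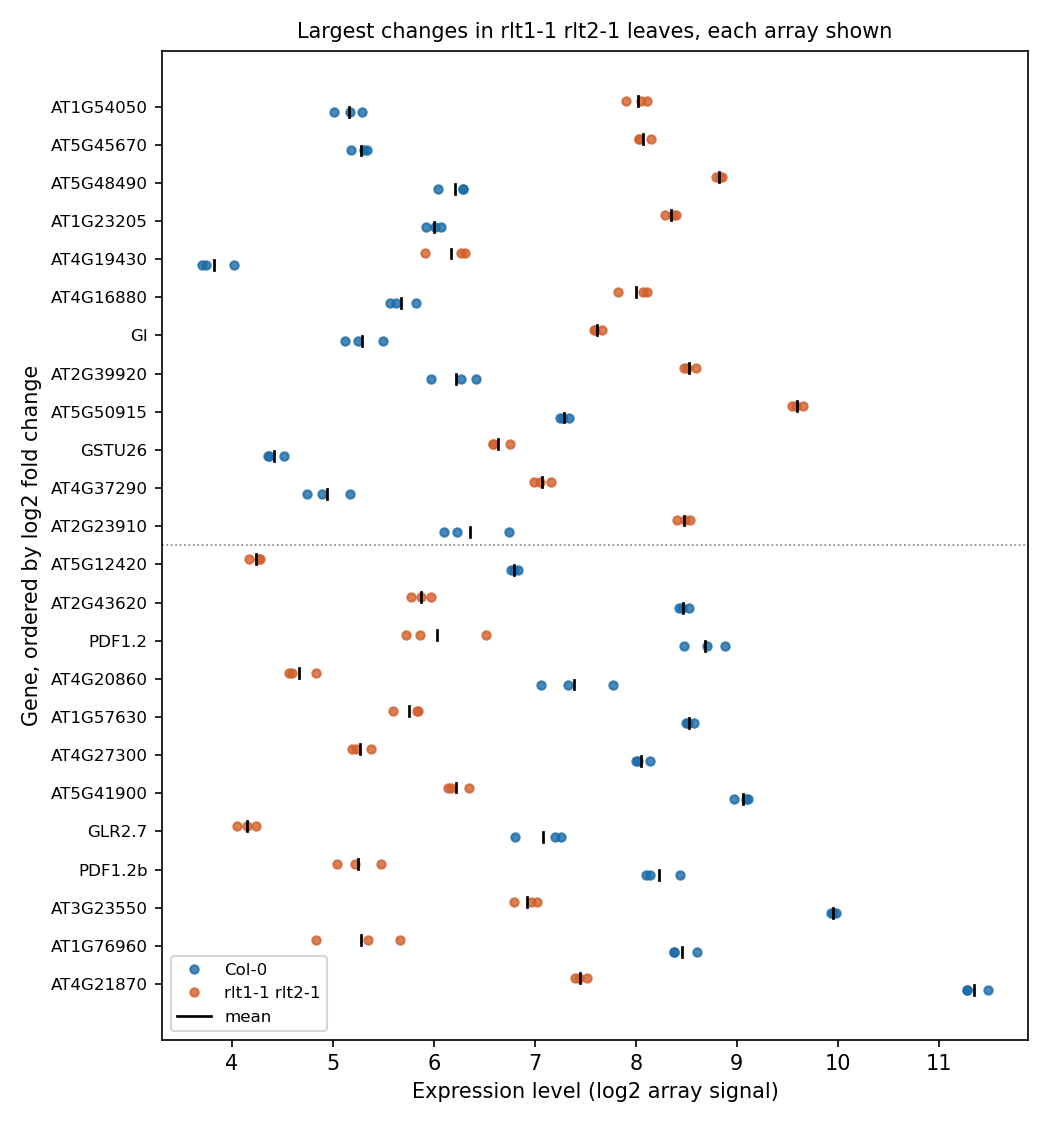
Expression of the 12 named genes with the largest increase and the 12 with the largest decrease in rlt1-1 rlt2-1 leaves, ordered by log2 fold change. The x axis gives the log2 array signal, each point is 1 array (3 per group, blue for Col-0 and orange for rlt1-1 rlt2-1), and black bars mark group means. The 2 groups do not overlap for any gene, and AT4G21870 at the bottom falls from 11.35 to 7.45.

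The gene lists fixed before the data were examined were covered only in small part, with 46 of 352 members on a named probe set, so each list stands for a few genes. These 46 are called measured below, while other members may lie on probe sets left unnamed here. Of these 46 genes, 7 were higher in the mutant, 13 were lower and 26 did not pass the test. The 20 called members lie near the share among all named probe sets, 5041 of 13436 (37.5%), so called members alone do not mark a list. Among unnamed probe sets the share was 45.4%. No list passed as a set in the main test described below. Of 4 measured cold and drought genes 3 fell: COR15A by 2.44-fold (log2 fold change -1.29 ± 0.06 SE, adjusted p = 1.42e-06), COR15B by 1.96-fold and COR47 by 1.93-fold, all of them genes of cold acclimation, while LTI30 was at 0.17 ± 0.08 (SE). Both measured genes of the touch and rapid wound response fell, the calmodulin-like gene CML38 by 2.14-fold and the zinc-finger gene ZAT10 by 1.42-fold. Of 3 measured senescence genes, the transcription factor genes WRKY6 and WRKY53 fell, with log2 fold changes of -0.84 ± 0.07 and -0.38 ± 0.06 (SE), and SAG29 was at 0.18 ± 0.06 (SE). Of 3 jasmonate and wounding genes PDF1.2 fell, as given above, THI2.1 was at -0.11 ± 0.11 and JMT at -0.41 ± 0.16 (SE).

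Of 4 measured auxin response genes 3 rose: HAT2, a homeodomain-leucine zipper gene, by 1.87-fold (log2 fold change 0.90 ± 0.08 SE, adjusted p = 4.72e-05), and the auxin-conjugating enzyme genes GH3.5 by 1.51-fold and GH3.3 by 1.36-fold (from 4.27, near the low end of the scale), while IAA29 was at -0.12 ± 0.07 (SE). The list did not pass as a set (camera, adjusted p = 0.238; 0.647 with an estimated correlation). Both measured gibberellin receptor genes fell, GID1A by 1.34-fold and GID1B by 1.22-fold. The call of GID1B ended when Col-0 replicate 2 or 3, or mutant replicate 2 or 3, was left out, with adjusted p between 0.0598 and 0.107. In the list of shoot meristem and leaf polarity genes PHV (PHAVOLUTA), which specifies the upper leaf side, fell 1.57-fold, YAB3 was at -0.08 ± 0.09 and CLV3 at 0.08 ± 0.07 (SE).

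Few flowering-time genes were on a named probe set. AGL19, a MADS-box gene that promotes flowering, rose by 0.58 ± 0.10 (SE) on the log2 scale (adjusted p = 0.00202), from 3.40 in Col-0 to 3.98, both near the low end of the scale. The other flowering activators AGL24, FD and AGL42 were at 0.20 ± 0.12, 0.11 ± 0.06 and -0.03 ± 0.08 (SE) and did not pass the test, nor did the repressors SMZ (-0.12 ± 0.11) and SNZ (0.06 ± 0.07). GI was the measured gene of the clock list. Of 2 glucosinolate genes BCAT4, of methionine chain elongation, fell 1.48-fold, and UGT74B1 was 1.11-fold higher at an adjusted p of 0.04998, a call that ended when any 1 array was left out. The call of UGT74B1 also ended in limma with the replicate number as a block (adjusted p = 0.0904) and with a further quantile normalization (adjusted p = 0.0523). AUR1, a mitotic Aurora kinase gene, rose 1.41-fold, and MCM7 was at 0.15 ± 0.10 (SE). INO80, the measured gene of the chromatin regulators, fell 1.40-fold, and its call ended without mutant replicate 3 (adjusted p = 0.0531). No member passed the test in the lists of photosynthesis (RCA at -0.11 ± 0.06 and LHCB4.1 at -0.02 ± 0.06), salicylic acid and defence (SAG101 at -0.38 ± 0.18 and GRX480 at 0.03 ± 0.05) and flavonoids (UF3GT at 0.15 ± 0.06, DFR at -0.20 ± 0.14 and UGT78D2 at 0.05 ± 0.08).

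The markers of other tissues gave no call. In the root list PYK10 was at -0.15 ± 0.09 and EXPA7 at -0.07 ± 0.07 (SE), and in the anther and carpel list AMS was at -0.15 ± 0.11 and SPL at -0.09 ± 0.08. UBC21, the 1 measured gene of 8 in the reference list, was at -0.04 ± 0.07. The array's own Arabidopsis controls did shift. Of 19 such probe sets 10 differed (limma, adjusted p under 0.05). The 6 higher ones were of actin and GAPDH, and the 4 lower ones of ubiquitin. The largest of these changes was 0.457 log2 units in size. The lists of floral identity, seed maturation, heat shock and vascular genes had 0 members on a named probe set and were not tested. Tested as sets against all other named genes with limma's camera at a preset correlation, 0 of the 20 lists with a measured member passed at an adjusted p under 0.05. The 3 lists with an unadjusted p under 0.05 were cold and drought (adjusted p = 0.0795), touch and wounding (adjusted p = 0.106) and the clock with its 1 gene (adjusted p = 0.135). With an estimated correlation 0 lists passed, with adjusted p = 0.540 for each of these 3. The clock list has 1 gene and so no correlation between genes, yet its unadjusted camera p went from 0.02025 to 0.08097. This setting has few degrees of freedom with 6 arrays, so its lack of passes does not show that correlation removed a shift. The self-contained test fry, which does not compare a list with other genes, passed 10 of the 20. Adjusted over the list alone, JMT and SAG29 also passed, which made 2 of 3 jasmonate genes and 3 of 3 senescence genes, and the counts of the other lists stayed as given.

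**Figure D2:**
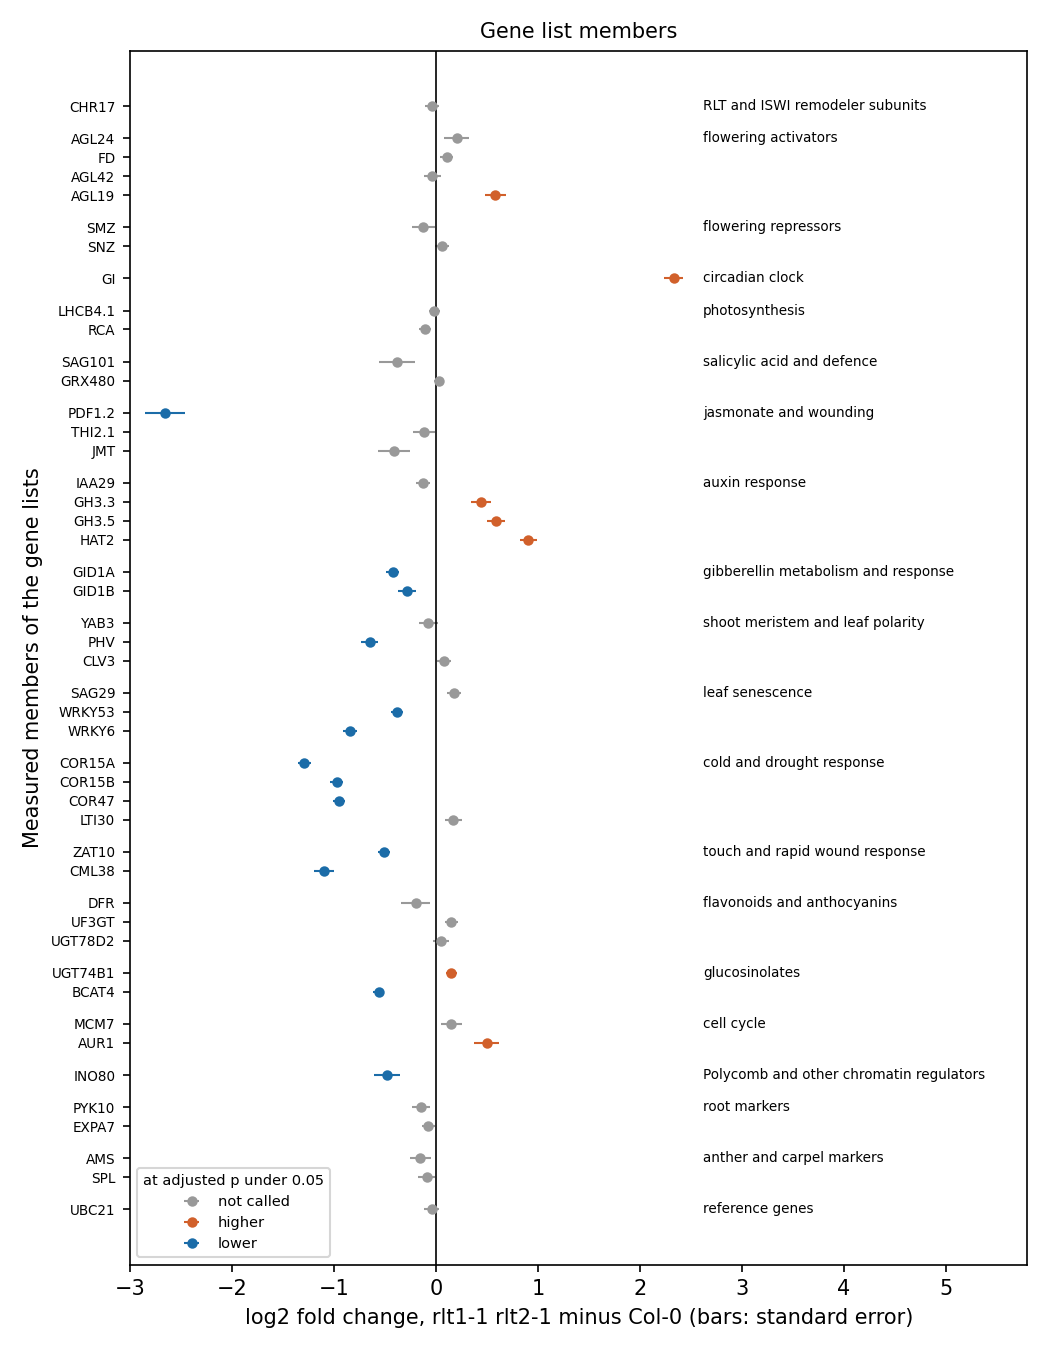
Change of each of the 46 list members on a named probe set in rlt1-1 rlt2-1 leaves, grouped by list. The x axis gives the log2 fold change against Col-0, points are fitted changes and bars are standard errors (3 arrays per group). Orange points passed as higher, blue as lower and grey points did not pass; GI at 2.33 and PDF1.2 at -2.65 lie farthest out.

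RNA quality was read from the array's own controls. The log2 difference between the 3' and 5' probe sets, averaged over 6 Arabidopsis control pairs, was 0.87 ± 0.05 (SD, n = 3) in Col-0 and 0.84 ± 0.01 in the mutant. The change of -0.03 had p = 0.5 in a two-sided exact permutation test, for which 0.1 is the smallest value that 3 arrays against 3 allow. The 6 pairs changed by between -0.143 and 0.084, with 4 lower and 2 higher.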

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

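The tests in this part were chosen only after the results were seen. The added spike controls, which stand outside the measurement of leaf RNA, drew attention because 9 of their 45 probe sets differed between the groups (limma, adjusted p under 0.05), 1 higher and 8 lower in the mutant, with a median change of -0.10 on the log2 scale. No spike probe set reached 2-fold. The called ones were 2 of 18 hybridisation spike probe sets (11.1%) and 7 of 27 Bacillus spike probe sets (25.9%).

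The first pattern is the breadth of the difference, with 9265 probe sets. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9265 probe sets, 1001 of them at 2-fold, and was the 1 split of 10 with counts as large, while the highest of the other splits gave 0 for both. Each other split mixes the 2 groups, so a large difference between the groups, whatever its cause, enters the spread and removes the calls. This contrast therefore cannot tell causes apart. A difference in hybridisation or scaling that the spikes share is argued against for the changes of at least 2-fold, since the largest spike change was 0.39 log2 units, but the copying and labelling of leaf RNA stay open there. For the small changes hybridisation, labelling and scaling stay open, as 20% of the spike probe sets were called against 40.7% of all probe sets, and so do the genotype, untested, and more degraded RNA in the mutant, since the 3' excess of the control pairs changed by -0.031 on average but went both ways over 3 transcripts.

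The second pattern is gene length: among 6026 named nuclear genes with a mean signal at or above the array median, the fold change fell with gene length (Spearman's rho = -0.22 across genes, which are not independent replicates; the largest absolute rho in 10000 permutations was 0.05). Length here is the span of the gene on the chromosome, which can differ from the length of its transcript. Transcript length was not used. In the tenth of genes with the shortest spans 282 rose and 139 fell, and in the tenth with the longest 85 rose and 281 fell. A bias with signal level is argued against by the slope, which was -0.13 log2 units per doubling of length and -0.12 after a smooth trend on mean signal was removed. A length effect that varies from array to array cannot be told apart from the genotype, because arrays of one group differed by slopes of up to 0.0398, against 0.0916 to 0.147 between groups (up to 0.0159 against 0.128 to 0.147 without Col-0 replicate 1), and the labels do not say whether the groups were labelled together; incomplete copying of long transcripts in the mutant stays open too, since the control pairs stand for 3 transcripts and went both ways. Length explained 2.88% of the variance of the fold changes, and with its trend removed 3890 of these genes differed instead of 3967, 3478 of them in both with the same sign.

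The third pattern is a lower level of plastid-encoded transcripts. Of 69 named plastid genes 27 fell and 1 (ndhG) rose, with a median log2 fold change of -0.26 and examples such as atpA (-1.30 ± 0.25 SE), psaB (-1.19 ± 0.14) and psbZ (-1.05 ± 0.19). As a group they passed camera (adjusted p = 0.00250 over 38 groups; adjusted p = 0.825 with an estimated correlation). A candidate explanation is variation between arrays in the copying of RNA without a poly(A) tail: the plastid median of Col-0 replicate 1 lay up to 0.47 log2 units above that of the other Col-0 arrays, more than the difference of -0.28 between the group means. Without Col-0 replicate 1 the group no longer passed (adjusted p = 0.0741), with a median of -0.15, 32 genes lower and 10 higher, and an effect of the genotype stays open, untested.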

How the results depend on the processing

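Of the alternatives here, the centring on spike controls, the restriction to larger lists and the removal of the length trend were chosen after the data were seen. No probe set called at first changed its sign under any setting of the fit and filter. The filters, the replicate block, the intensity trend and the unmoderated test leave each fold change as it was, so the sign was fixed there. The count of probe sets that differed stayed between 7534 and 10992 under all settings of the fit and filter. The lowest, 7534, was out of the 11373 probe sets left without the dimmest 50%, a larger share than 9265 of 22746 in the main fit. At an adjusted p under 0.01 it was 6901. Leaving out each array in turn, with all 22746 probe sets, gave 7873 to 9987. The count at 2-fold stayed between 817, from the same filter, and 1033, and a limit of 1.5-fold gave 3029 by its looser construction. The replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated at -0.01, 0.01 and 0.05, and the replicate block gave 8957 probe sets. The fold changes of RLT1 and RLT2 and the alternatives planned for them were not run. No list passed in the planned test, in which leaving out each array gave 0 throughout. With an intensity trend and robust prior 2 passed, cold (adjusted p = 0.0190) and touch (0.0472); with spike centring 1 passed, cold (0.0310), as did 1 with lists of at least 3 genes, cold again (0.0278), where fewer lists were tested. With the planned fit and an estimated correlation 0 lists passed (cold and touch 0.540 each). By fry 10 passed: cold (0.000112), clock (0.000224), touch (0.000224), senescence (0.000612), photosynthesis (0.00110), auxin (0.00110), glucosinolates (0.00335), meristem and leaf polarity (0.00464), gibberellin (0.0136) and jasmonate (0.0241). The cause of these changes was not tested. Of the 10 lists that passed by fry, 2 were higher and 8 lower. A pass by fry did not need called members, since neither measured photosynthesis gene was called in the main test. Fry also passed most of the symbol groups described below, where 37.5% of named probe sets differed in the main test. An example is SBT (fry, adjusted p = 0.00784), with 1 of 8 genes higher and 1 lower. A pass by fry therefore does not mark a list. The 2 measured glucosinolate genes went opposite ways. Of 42 named genes that were called, 37 kept call and sign in every setting in which they were tested; 8 of the 42, GH3.5 and AGL19 among them, fell out under a filter in at least 1 of 16 settings, and of the 34 tested in all, 30 kept both. GID1B, UGT74B1, INO80, GH3.3 and AUR1 lost the call in at least 1, and none reversed. The 42 include the 12 largest rises and the 12 largest falls, whose size makes a lost call or a reversal unlikely. RCA, UF3GT and DFR, not called at first, gained a call in some settings, in 7 values in all. Genes near the low end of the scale, such as AGL19, are limited by signal over background.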

Other observations

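The CML, SEC, LSM and other symbol groups in this part were defined after the data were seen, from gene symbols alone. The plastid group was also formed then, from the location of the genes. Only the fixed lists, named for the splits of the arrays, were set before. Of 7 calmodulin-like (CML) genes, which encode calcium sensors, 5 fell in the mutant: CML37 (log2 fold change -1.96 ± 0.07 SE), CML38 (-1.09 ± 0.10), CML42 (-1.05 ± 0.05), CML41 (-0.96 ± 0.11) and CML30 (-0.75 ± 0.08), while CML23 rose (0.28 ± 0.09) and CML43 was at 0.02 ± 0.06. Of 9 genes with SEC symbols 7 fell, among them SEC6 (-0.84 ± 0.08), SEC10 (-0.60 ± 0.06) and SEC15B (-0.46 ± 0.06) of the exocyst, the complex that tethers secretory vesicles, and also SEC1B (-0.78 ± 0.07) and SEC (-0.64 ± 0.08), which are not exocyst subunits. The exocyst genes SEC15A (0.11 ± 0.06) and SEC5B (-0.14 ± 0.06) did not pass the test. Of 6 LSM genes, which encode RNA-binding ring proteins of splicing and mRNA decay, 5 rose, with LSM3A (0.76 ± 0.09) and LSM1B (0.68 ± 0.06) foremost. By camera over 38 groups, plastid genes included, SEC (adjusted p = 0.00451), CML (0.0114) and LSM (0.0274) passed, and none did with an estimated correlation (adjusted p = 0.584 for SEC and CML, 0.797 for LSM). That setting has few degrees of freedom with 6 arrays, as given above. Without the dimmest 50% of probe sets CML (0.383) and LSM (0.193) no longer passed; LSM was also lost without the dimmest 30% (0.113), without Col-0 replicate 3 (0.0598) and with spike centring (0.0667). The groups differ in gene length, with median spans of 6063 bases for SEC, 1418 for LSM and 981 for CML, and among the brighter named genes the fold change fell with length, as given above. With a trend on gene length removed over the nuclear genes, SEC (adjusted p = 0.0766 over 37 groups; 0.00853 before on the same genes) and LSM (0.0766; 0.0371 before) no longer passed and CML did (0.0199); the mean log2 fold change of SEC went from -0.43 ± 0.32 (SD over genes) to -0.32 ± 0.29 with 6 of 9 lower, and that of LSM from 0.45 ± 0.25 to 0.40 ± 0.25 with 4 of 6 higher. The direction of these groups was kept under every scaling tried. Of the 10 splits of the arrays, the real one gave 4 such groups by camera at the preset correlation. Each of the others gave between 1 and 3, though 0 probe sets differed in any of them. Groups thus passed at this setting without any called probe set. For the fixed lists the real split gave 0 and the highest other 1, so that all 10 gave as many. The 10 splits are too few for a share under 0.05.

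Beside GI, 2 genes picked after their values were seen rose, the cold- and clock-regulated gene COR27 (0.91 ± 0.05 SE) and AT4G33980 (1.63 ± 0.06). The time of day at harvest was not given in the sources used here. Other genes picked in the same way fell: AT1G26380 (-2.065 ± 0.071 SE), AT1G26420 (-1.634 ± 0.105), AT5G44400 (-1.376 ± 0.095) and AT4G20830 (-0.45 ± 0.06). The 100 measured genes around RLT1 held 30 that differed and those around RLT2 47, which puts them at percentiles 18.0 and 88.8 of all windows of 100 neighbouring genes. Neighbouring genes changed alike only weakly, with Spearman's rho = 0.03 over 13211 adjacent pairs (one-sided permutation p = 0.0002 with 10000 permutations).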
